A study of Mus musculus with 6 samples.

How the data were processed

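RNA was measured by sequencing in the right hippocampus of male C57BL/6J mice. Per the labels, 3 samples came from the Sham group and 3 from mice with transient middle cerebral artery occlusion (tMCAO), in which a filament closed the artery for 50 min before reperfusion. The animals were perfused with saline before dissection, and libraries were made from poly(A)-selected RNA. The time between occlusion and tissue collection is not given in the sources used here.

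The deposited values are FPKM, reads or fragments scaled by gene length and by a factor for each library, computed by the authors. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. A table of 53465 genes and a comparison table of 22647 genes held the same 6 libraries, and their FPKM differed by at most 1.8e-12. The comparison table also held a log2 fold change, a p-value and an adjusted p-value from the authors' own deposited comparison. The test behind them is not given in the sources used here. Its sign is Sham over tMCAO, so a negative value means higher in tMCAO. The Sham columns were matched to samples by title. The tMCAO columns name the group and not the sample, so tMCAO 1 to 3 are the numbers of the columns.

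Depth was read from the FPKM themselves. In each of the 36452 genes above 0 in any library, the values were whole multiples of the worth of 1 read (tolerance 1e-10), which gave whole reads for 100% of these genes. Genes above 0 in only 1 or 2 libraries meet this rule by construction, so the share has weight only for the other genes. The exon length implied by the worth of 1 read equalled the union exon length of GENCODE release M21 within 0.1% for 20913 of the 22647 compared genes (92.3%). The reads assigned to genes came to 39196506, 42474243 and 46477443 in Sham 1, 2 and 3 and to 58209500, 58172979 and 66438726 in tMCAO 1, 2 and 3. Whether a unit is a read or a read pair is not known. Relative to Sham 1, the worth of 1 read implied a depth of 1.047 in Sham 2 and 1.609 in tMCAO 3. The assigned reads gave 1.084 and 1.695, so the authors' library factor need not follow the reads assigned to genes.

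The comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), without rescaling, over the 17561 genes of the comparison table whose mean FPKM over the 6 libraries was at least 0.5. The fit used lmFit and eBayes with a mean-variance trend, a two-sided test and Benjamini-Hochberg adjustment, with adjusted p below 0.05 as the threshold. A fold change on this scale understates the change of genes with low FPKM. Beside it, an exact two-sided permutation test of 20 assignments was run for each named gene, which with 3 libraries against 3 cannot give p below 0.10. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples.

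Before the data were examined, 50 gene lists, the design, the alternatives and the rule for naming genes were fixed. Lists with at least 5 tested genes (48 lists) were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way and compares them with no other genes, were run beside it. The genes named are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap, without predicted models. To these come up to 4 members of each described list with the smallest adjusted p, or the 2 with the highest FPKM where none passed. P2ry12, Cnr2, Cnr1, Gfap, Aif1, Cd68, Tnf, Il1b and Il6 were named whatever their values. Genes outside this rule are said to be so. The single results of 3 genes are not reported here, while the tests and counts include these genes.

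The procedure was tested on simulated data with 17391 genes at the observed means and spread. It called 13 of 50 genes changed 1.5-fold, 28 of 50 changed 2-fold, 47 of 50 changed 4-fold and 46 of 50 changed 8-fold, with 6 false calls. Only 200 genes were changed there, whereas 2847 were called in the data. The adjusted threshold depends on this number, so these rates need not hold for the data. Camera called 10 of 10 raised lists of 20 genes and 0 of 40 unchanged lists. The simulated genes were drawn independently, so this says nothing about lists whose genes vary together, as those of the real lists do.

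Of the alternatives, 18 were planned: another pseudocount (0.1), no filter, a mean FPKM of at least 2, 3 other scalings, eBayes without trend, library weights, a log2 fold change of at least 1, the table of all genes, both list tests and leaving out each library. After seeing the data, 5 were added: voom on the recovered reads, thinning to the shallowest library, removal of the trend on exon length, a striatal score as covariate, and leaving out Sham 2 with tMCAO 3. In addition, 3 further gene lists were composed after the leading genes had been seen. Positions are from GENCODE M21 on mm10. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.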

Results

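The series measured gene expression in the right hippocampus of mice after a Sham operation (3 libraries) and after tMCAO, a model of ischemic stroke with reperfusion (3 libraries). The title of the series names the microglial receptors CB2R, encoded by Cnr2, and P2Y12, encoded by P2ry12, together with physical exercise. The labels of these 6 samples give the Sham and tMCAO groups only, and exercise was not analysed here. Reads assigned to genes numbered 39196506 to 46477443 per Sham library and 58172979 to 66438726 per tMCAO library, so each tMCAO library was deeper than each Sham library.

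After tMCAO, 14 of 16 pan-reactive astrocyte genes, 10 of 21 NF-kB and TLR genes and 13 of 23 apoptosis genes and p53 targets rose, while 10 of 18 homeostatic microglial genes fell. These lists passed camera at its preset correlation, and each had an adjusted p = 0.58 with an estimated correlation. Fry gave adjusted p of 0.031, 0.02, 0.02 and 0.02 in the order named. Cdkn1a, the cell cycle inhibitor p21, rose from 8.29 ± 1.72 to 83.1 ± 23.2 FPKM (SD, n = 3 per group). Timp1, an inhibitor of matrix metalloproteinases, rose from 1.34 ± 0.435 to 19.3 ± 6.22 FPKM, and Ctla2a, a cysteine protease inhibitor that shares 16.3% of its exon length with other genes, from 0.884 ± 0.282 to 19.8 ± 4.4 FPKM. P2ry12 fell from 11.4 ± 2.01 to 2.89 ± 0.683 FPKM, and Gpr34, another microglial receptor, from 4.05 ± 0.697 to 0.579 ± 0.279 FPKM. In all, 2847 of 17561 tested genes passed the limma test, 1569 higher and 1278 lower in tMCAO, and 239 of them changed by at least 1 on the log2 scale (177 higher, 62 lower). With the libraries rescaled to an equal sum, the split was 1055 higher and 1533 lower. The count of genes that changed by at least 1 depended on the scale: it was 612 (369 higher, 243 lower) with a pseudocount of 0.1, 503 (271 and 232) with rescaled libraries and 640 (350 and 290) with voom on recovered reads, chosen after seeing the data. It was 87, 152 and 61 without Sham 1, 2 and 3. Groups did not overlap in 7627 tested genes, 43.4% against the 10% that chance gives.

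The count of changed genes varied when 1 library was left out, with fewer samples in each fit. It was 124, 419 and 75 without Sham 1, 2 and 3, and 1523, 2183 and 3896 without tMCAO 1, 2 and 3. Of the 124, 419 and 75 genes, 122, 412 and 74 were among the 2847 in the same direction. Genes with an unadjusted limma p below 0.05 numbered 6317 with all 6 libraries. They numbered 4631, 4879 and 4382 without Sham 1, 2 and 3, and 5575, 5972 and 7104 without tMCAO 1, 2 and 3. Among the 2847 genes, 68 passed in each of these 6 fits, 53 of them higher in tMCAO. They include P2ry12, Gpr34, Siglech, Itm2a, Slc22a8, Ugt8a, Tek, Cdkn1a, Timp1, Ctla2a, Adamts1, Maff, Nfkbia, Fcgr3, C5ar1, Osmr, Fkbp5, Fosl1 and Mfsd2a. Fosl1 shares 57.2% of its exon length with Ccdc85b on the opposite strand, so its reads are uncertain. Of 149 genes past the threshold under the rule for naming genes, 122, 95 and 128 lost their call without Sham 1, 2 and 3, and 49, 37 and 5 without tMCAO 1, 2 and 3. The highest adjusted p among these fits was 0.16.

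**Figure D1:**
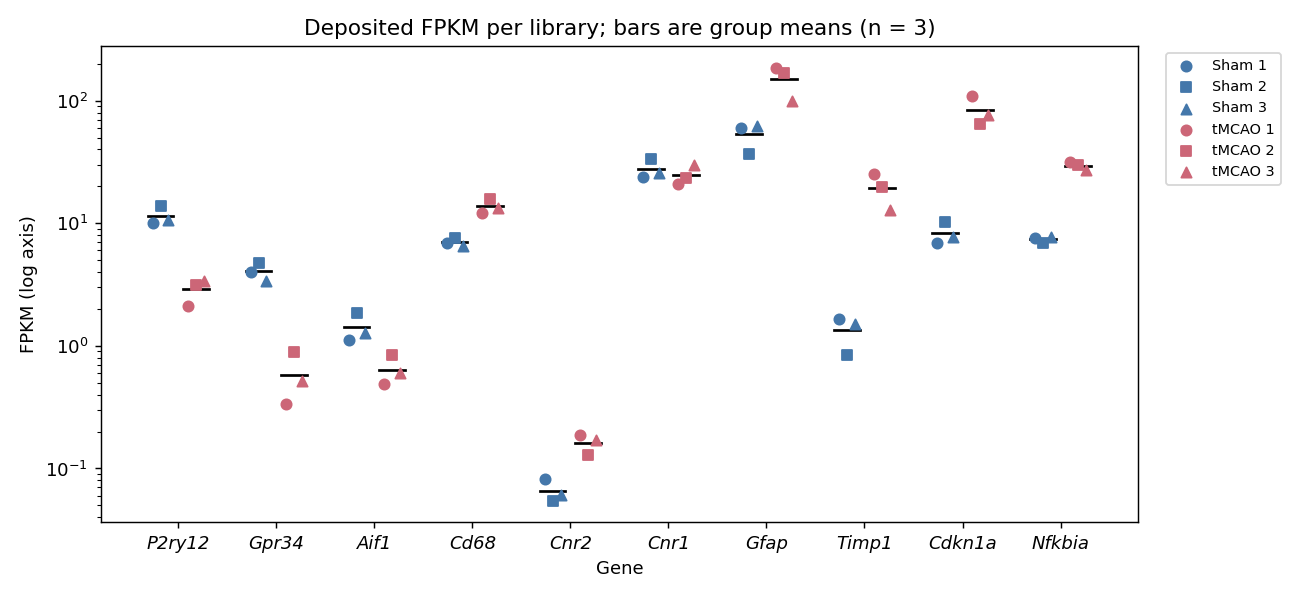
Deposited FPKM of 10 genes (log axis) in each of the 3 Sham and 3 tMCAO libraries, with group means as bars. P2ry12 lies at 9.98 to 13.7 FPKM in Sham and at 2.11 to 3.4 FPKM in tMCAO, and Cnr2 stays below 0.2 FPKM in each library.

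P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871, minus strand) had a log2 fold change of -1.68 (SE 0.17, limma adjusted p = 0.0062), and the exact permutation test gave p = 0.10. It shares 0.4% of its exon length with Med12l on the opposite strand. Homeostatic microglial genes, which mark surveying microglia, fell as a list: 10 of 18 tested members fell, none rose and 8 did not pass (11 lower adjusted over the list alone). The list's median log2 fold change was -0.73, with a camera adjusted p = 2e-06 and an adjusted p = 0.58 with an estimated correlation. Siglech fell from 3.82 ± 0.56 to 1.28 ± 0.112 FPKM and Slc2a5, a fructose transporter, from 1.07 ± 0.0579 to 0.251 ± 0.0347 FPKM. Not all members moved this far: Csf1r, the growth factor receptor of microglia, was at 15.5 ± 1.32 and 13.3 ± 0.977 FPKM (adjusted p = 0.14), and was chosen after its values were seen. Aif1, which encodes the microglial marker Iba1, fell from 1.41 ± 0.399 to 0.641 ± 0.177 FPKM (adjusted p = 0.043), and this call was lost in each leave-one-out fit (adjusted p up to 0.12), with quantile normalization (0.05) and with library weights (0.063).

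Cnr2 lay below the expression filter. It was at 0.0659 ± 0.0149 FPKM in Sham (33 reads in all) and 0.163 ± 0.0307 FPKM in tMCAO (116 reads in all), and without a filter the limma adjusted p was 0.074. The authors' deposited table gives a log2 fold change of -1.31 (Sham over tMCAO) with an adjusted p of 0.045. Cnr1, the neuronal cannabinoid receptor, was at 27.8 ± 5.19 and 24.7 ± 4.8 FPKM (adjusted p = 0.51). None of 12 tested endocannabinoid genes passed, also adjusted over the list alone (camera adjusted p = 0.53). The nearest, Gde1 (limma adjusted p = 0.052), passed as higher with library weights (0.046) and with the striatal covariate (0.029). Of 16 purinergic receptors and ectonucleotidases, P2ry12 and P2ry13 fell and Ada, adenosine deaminase, rose, with the same counts adjusted over the list alone (camera adjusted p = 0.66).

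Disease-associated microglial genes included 5 of 20 that rose and 1 that fell, and 7 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.00093, adjusted p = 0.58 with an estimated correlation). The mean log2 deviation of this list was 0.34 and 0.42 in tMCAO 1 and 2 and -0.02 in tMCAO 3, against -0.27 to -0.22 in Sham. Cd68, a lysosomal protein of phagocytes, rose from 7.03 ± 0.515 to 13.8 ± 1.79 FPKM (adjusted p = 0.0099, lost without Sham 1 or Sham 3 with an adjusted p of up to 0.055). Spp1, osteopontin, rose from 10.4 ± 3.17 to 41.7 ± 21 FPKM, with 18.8% of its exon length shared with Gm42793, and Lgals3, galectin-3, from 0.465 ± 0.155 to 3.79 ± 1.74 FPKM. The lipid-sensing receptor gene Trem2 was the member that fell, from 2.01 ± 0.252 to 1.2 ± 0.209 FPKM, and was chosen after its values were seen.

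**Figure D2:**
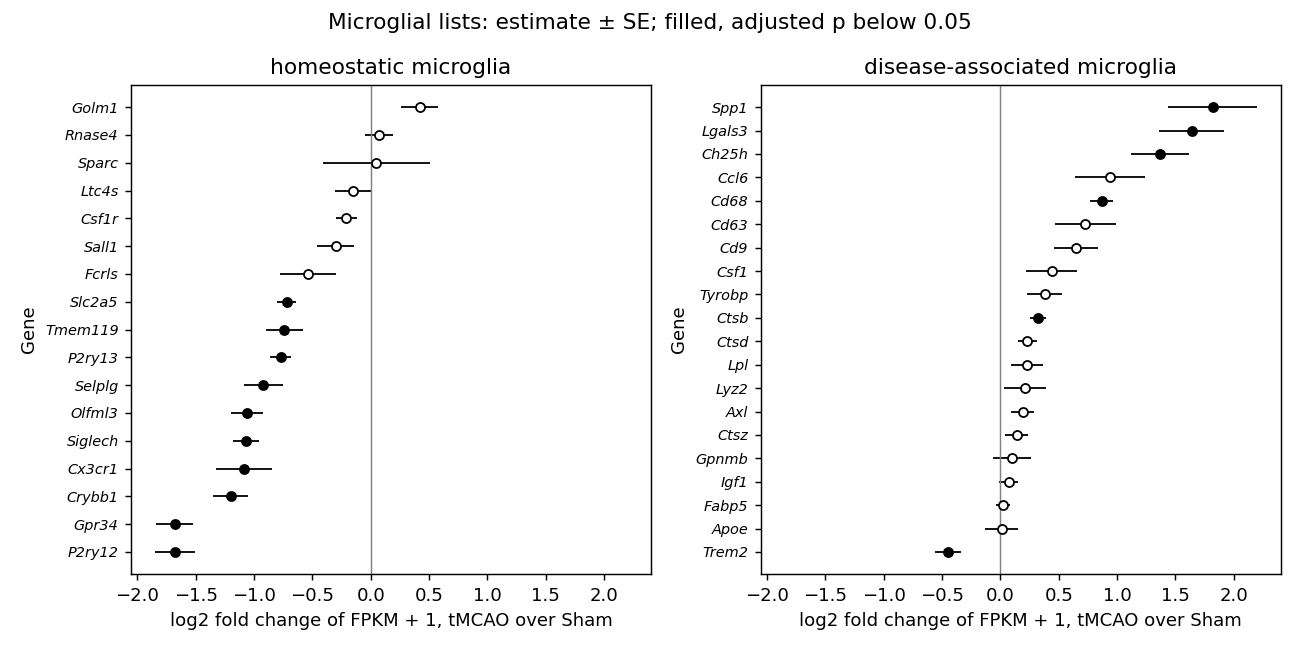
Log2 fold change of FPKM + 1 (tMCAO over Sham) with its SE for 17 of the 18 homeostatic (left) and the 20 disease-associated (right) microglial genes tested, filled where adjusted p was below 0.05. Filled points lie left of 0 for 10 homeostatic genes and right of 0 for 5 disease-associated genes.

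Pan-reactive astrocyte genes, induced in astrocytes by many injuries, rose in 14 of 16 cases (15 adjusted over the list alone), with a median log2 fold change of 1.31 (camera adjusted p = 1.3e-09, adjusted p = 0.58 with an estimated correlation). Serpina3n, a protease inhibitor, rose from 12.4 ± 2.64 to 76.8 ± 28.4 FPKM, and Osmr, the oncostatin M receptor, from 0.454 ± 0.0549 to 3.1 ± 0.592 FPKM. Gfap, the astrocyte intermediate filament gene, rose from 52.9 ± 14.1 to 151 ± 46.0 FPKM (log2 fold change 1.48, SE 0.29, adjusted p = 0.022). Its call was lost without Sham 1, 2 or 3 and without tMCAO 1 or 2 (adjusted p up to 0.075). The list named A2 rose in 10 of 11 genes (11 adjusted over the list alone, camera adjusted p = 2e-06) and the list named A1 in 4 of 11 (6 adjusted over the list alone, camera adjusted p = 0.0032). For both the adjusted p was 0.58 with an estimated correlation. Cd14, a lipopolysaccharide co-receptor counted in the A2 list, rose from 1.19 ± 0.379 to 21.5 ± 13.5 FPKM, and Fkbp5, a glucocorticoid-induced co-chaperone counted in the A1 list, from 7.47 ± 1.01 to 21.1 ± 2.9 FPKM. General astrocyte markers went both ways: 3 of 16 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.66).

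Among cytokines and chemokines, 7 of 20 tested genes rose and 1 fell (12 and 2 adjusted over the list alone, median 1.17, camera adjusted p = 0.00044, adjusted p = 0.68 with an estimated correlation, and 0.13 at a mean FPKM of at least 2). The monocyte chemoattractant Ccl2 rose from 0.0634 ± 0.0454 to 6.54 ± 4.05 FPKM and Ccl3 from 0.326 ± 0.249 to 9.06 ± 5.24 FPKM. In tMCAO 3 both were lower (2.02 and 3.02 FPKM) than in the other tMCAO libraries. Tnf, Il1b and Il6, classical inflammatory cytokines, lay below the filter, at 0.465 ± 0.255, 0.656 ± 0.418 and 0.694 ± 0.613 FPKM in tMCAO and at 0.0143 ± 0.0148, 0.123 ± 0.0238 and 0.0232 ± 0.0165 FPKM in Sham. Without a filter their limma adjusted p were 0.04, 0.091 and 0.099, on a scale that compresses low values. Reads over the group were 3 in Sham and 134 in tMCAO for Tnf, 30 and 219 for Il1b and 7 and 296 for Il6. The authors' deposited table gives log2 fold changes (Sham over tMCAO) of -5.01 for Tnf, -2.41 for Il1b and -4.92 for Il6, with adjusted p of 5.7e-05, 0.0013 and 6.3e-07. NF-kB and TLR genes rose in 10 of 21 cases (11 adjusted over the list alone, camera adjusted p = 4.1e-06), including Nfkbia, the inhibitor of NF-kB, which rose from 7.39 ± 0.415 to 29.5 ± 2.06 FPKM. Complement genes rose in 5 of 16 cases (6 adjusted over the list alone, camera adjusted p = 0.022, 0.091 without tMCAO 2 and 0.13 at a mean FPKM of at least 2), among them the receptor gene C5ar1, from 0.393 ± 0.0648 to 2.85 ± 0.177 FPKM. Genes of phagocytosis and lysosomes rose in 9 of 24 cases and fell in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00095, and 0.06 at a mean FPKM of at least 2), with the Fc receptor gene Fcgr3 at 6.17 ± 0.367 and 18.6 ± 1.68 FPKM. With an estimated correlation the adjusted p was 0.58 for the NF-kB and phagocytosis lists and 0.6 for complement.

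Markers of monocytes and macrophages rose in 4 of 10 cases (6 higher and 1 lower adjusted over the list alone, median 0.63, camera adjusted p = 0.0099, adjusted p = 0.58 with an estimated correlation). The adhesion receptor gene Cd44 rose from 0.673 ± 0.317 to 3.45 ± 1.78 FPKM (adjusted p = 0.041, and 0.059 with voom on recovered reads). The Cd44 call was also lost without Sham 1, 2 or 3 and without tMCAO 1 or 2 (limma adjusted p up to 0.12). Of 7 tested neutrophil genes, only Lcn2, which reactive astrocytes also express, passed (1 adjusted over the list alone, camera adjusted p = 0.18). Inflammasome (1 of 9 higher), interferon-stimulated (3 of 22 higher) and antigen presentation genes (2 of 16 higher) had camera adjusted p of 0.47, 0.47 and 0.56, with the same counts adjusted over the list alone. No lymphocyte gene of 4 passed, also adjusted over the list alone.

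Apoptosis genes and p53 targets rose in 13 of 23 cases and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 4.3e-06), including Cdkn1a and Mdm2, the p53 ligase, at 7.7 ± 0.0779 and 11.3 ± 0.493 FPKM. NRF2 target genes of the oxidative stress response rose in 9 of 21 cases (13 adjusted over the list alone, camera adjusted p = 2.5e-06), and Mt2, a metallothionein, went from 120 ± 8.24 to 504 ± 265 FPKM. Mt2 shares 73.5% of its exon length with Gm45774 on the opposite strand, so its reads are uncertain. Heat shock and unfolded protein genes rose in 5 of 22 cases (5 adjusted over the list alone, camera adjusted p = 0.00015), among them Hspb1, from 4.0 ± 0.516 to 37.5 ± 28.2 FPKM (adjusted p = 0.032, and 0.075 with voom on recovered reads). The Hspb1 call was also lost without Sham 1, 2 or 3 and without tMCAO 1 or 2 (limma adjusted p up to 0.11). The mean log2 deviation of the heat shock list was 0.93 and 0.61 in tMCAO 1 and 2 but -0.32 in tMCAO 3, close to the Sham libraries (-0.42 to -0.39). Hypoxia and glycolysis genes rose in 4 of 21 cases and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.019, 0.13 at a mean FPKM of at least 2 and 0.078 with quantile normalization). Slc2a1, the glucose transporter of the blood-brain barrier, rose from 29.0 ± 1.38 to 41.6 ± 3.3 FPKM, whereas Vegfa, a growth factor, fell from 20.2 ± 2.23 to 13.7 ± 2.26 FPKM. With an estimated correlation the adjusted p was 0.58 for the p53, NRF2 and hypoxia lists and 0.68 for heat shock. Ferroptosis and iron genes, with Hmox1, heme oxygenase 1, at 2.58 ± 0.332 and 25.1 ± 15.7 FPKM, rose in 6 of 16 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.076, but 0.032 without Sham 3, 0.015 without tMCAO 3 and 0.024 without Sham 2 and tMCAO 3).

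Ribosomal protein genes rose in 13 of 26 cases (25 adjusted over the list alone, median 0.49, camera adjusted p = 1.3e-09, adjusted p = 0.59 with an estimated correlation), for example Rps14 from 92.7 ± 1.31 to 147 ± 11 FPKM. Many of these genes have processed pseudogenes with which reads could be shared. Nuclear genes of the respiratory chain rose in 8 of 24 cases (14 adjusted over the list alone, median 0.26, camera adjusted p = 4.4e-05, adjusted p = 0.68 with an estimated correlation), and Cox4i1 went from 180 ± 6.2 to 236 ± 18.9 FPKM. The 13 mitochondrially encoded genes had no call, also adjusted over the list alone (camera adjusted p = 0.66). Across 13722 protein-coding genes, the log2 fold change fell with exon length (Spearman rho -0.2 across genes, which are not independent replicates), from a median of 0.09 in the shortest of 10 length classes to -0.12 in the longest. Between these classes the median deviation from the mean of all libraries ran from 0.13 to -0.11 in tMCAO 1 and from 0.05 to -0.05 in tMCAO 2, but from -0.03 to 0.02 in tMCAO 3, close to Sham 1 (-0.03 to 0.03).

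Postsynaptic and glutamate receptor genes fell in 7 of 26 cases (7 adjusted over the list alone, median -0.3, camera adjusted p = 1e-04, adjusted p = 0.6 with an estimated correlation). Grm3, a metabotropic glutamate receptor, fell from 17.1 ± 1.87 to 6.48 ± 1.41 FPKM and Shank1, a scaffold protein, from 54.0 ± 2.12 to 31.4 ± 3.81 FPKM. GABA-A receptor genes fell in 4 of 13 cases (5 adjusted over the list alone, camera adjusted p = 0.0094, adjusted p = 0.58 with an estimated correlation). Voltage-gated ion channel genes fell in 3 of 25 (3 adjusted over the list alone, camera adjusted p = 0.00037, adjusted p = 0.6 with an estimated correlation), including Scn2b, a sodium channel subunit, from 54.3 ± 3.09 to 35.2 ± 4.93 FPKM. The mean log2 deviation of the channel list in tMCAO 3 (0.12) lay within that of the Sham libraries (0.05 to 0.23), apart from tMCAO 1 and 2 (-0.3 and -0.21). For the postsynaptic list it was -0.35, -0.16 and 0.02 in tMCAO 1, 2 and 3, against 0.09 to 0.2 in Sham. For the GABA-A list it was -0.27, -0.18 and 0.01, against 0.08 to 0.18 in Sham. Presynaptic genes fell in 4 of 25 cases, the same adjusted over the list alone (camera adjusted p = 0.12, but 0.015 without tMCAO 3, 0.0062 with quantile normalization, 0.019 with library weights and 0.02 without Sham 2 and tMCAO 3), with Unc13a at 37.8 ± 3.53 and 19.2 ± 3.53 FPKM. Markers of excitatory (2 higher, 2 lower of 18), pyramidal (1 and 1 of 15), dentate granule (0 and 2 of 14) and inhibitory neurons (1 and 1 of 17) had camera adjusted p of 0.43, 0.98, 0.12 and 0.58, with the same counts adjusted over the list alone. The excitatory list had a camera adjusted p of 0.032 without tMCAO 3 and 0.031 without Sham 2 and tMCAO 3, and the dentate list one of 0.025 without Sham 2 and 0.0053 with a striatal covariate. Of 24 immediate early genes, 7 rose (8 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.12, but 0.025 without Sham 3, 0.0061 without tMCAO 3, 0.036 when rescaled and 0.013 without Sham 2 and tMCAO 3), with the transcription factor gene Maff at 0.577 ± 0.0981 and 8.6 ± 2.3 FPKM. Growth factors (1 higher, 2 lower of 16, and 1 and 3 adjusted over the list alone) had a camera adjusted p of 0.19, and 0.028 without tMCAO 1. Neurogenesis (1 and 1 of 13) and proliferation genes (3 higher of 12) had camera adjusted p of 0.9 and 0.19, with the same counts adjusted over the list alone. The proliferation list had a fry adjusted p of 0.02, as higher.

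Oligodendrocyte genes fell in part. Of mature oligodendrocyte genes, 5 of 18 fell (7 adjusted over the list alone, median -0.38, camera adjusted p = 0.0032, adjusted p = 0.69 with an estimated correlation), and without tMCAO 3 the list's adjusted p was 0.11. The mean log2 deviation of the list was lowest in tMCAO 3 (-0.6), where striatal markers were high and choroid plexus markers low, while tMCAO 1 (0.11) lay within the Sham libraries (0.03 to 0.28) and tMCAO 2 was at -0.09. Ugt8a, an enzyme of myelin lipid synthesis, fell from 12.5 ± 0.866 to 4.15 ± 0.862 FPKM. Precursor genes fell in 6 of 13 cases (6 adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.58 with an estimated correlation, with the call lost at 0.05 without Sham 3 and at 0.16 without tMCAO 3), among them Gpr17, from 10.1 ± 0.346 to 5.2 ± 1.85 FPKM. This call was also lost in 5 other settings, with an adjusted p of 0.052 when rescaled, 0.075 with library weights, 0.13 at a mean FPKM of at least 2, 0.1 with the length trend removed and 0.17 without Sham 2 and tMCAO 3. Cholesterol synthesis genes had 1 of 21 lower (1 adjusted over the list alone), the regulator Srebf2. The list's camera adjusted p was 0.033, 0.77 with an estimated correlation, and 0.065, 0.14 and 0.2 without Sham 1, tMCAO 2 and tMCAO 3. It was 0.053 without a filter and 0.2 without Sham 2 and tMCAO 3.

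Endothelial genes moved apart: 4 of 20 rose and 9 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.3). Mfsd2a, a lipid transporter, rose from 11 ± 0.806 to 22.3 ± 1.9 FPKM, while Tek, the angiopoietin receptor, fell from 3.22 ± 0.16 to 0.822 ± 0.279 FPKM and Itm2a, a membrane protein, from 18.9 ± 2.06 to 5.97 ± 0.517 FPKM. Genes of endothelial activation rose in 6 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.68 with an estimated correlation, 0.11 without tMCAO 2 and 0.13 at a mean FPKM of at least 2). The mean log2 deviation of this list was -0.13 in tMCAO 3, nearer to the Sham libraries (-0.43 to -0.28) than to tMCAO 1 and 2 (0.58 and 0.65). Mural cell genes (3 of 13 lower) had a camera adjusted p of 0.065, and 0.046 and 0.047 without Sham 3 and tMCAO 2. Their fry adjusted p was 0.041. Fibroblast genes (1 of 15 lower) had a camera adjusted p of 0.33. Both lists had the same counts adjusted over the list alone.

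**Figure D3:**
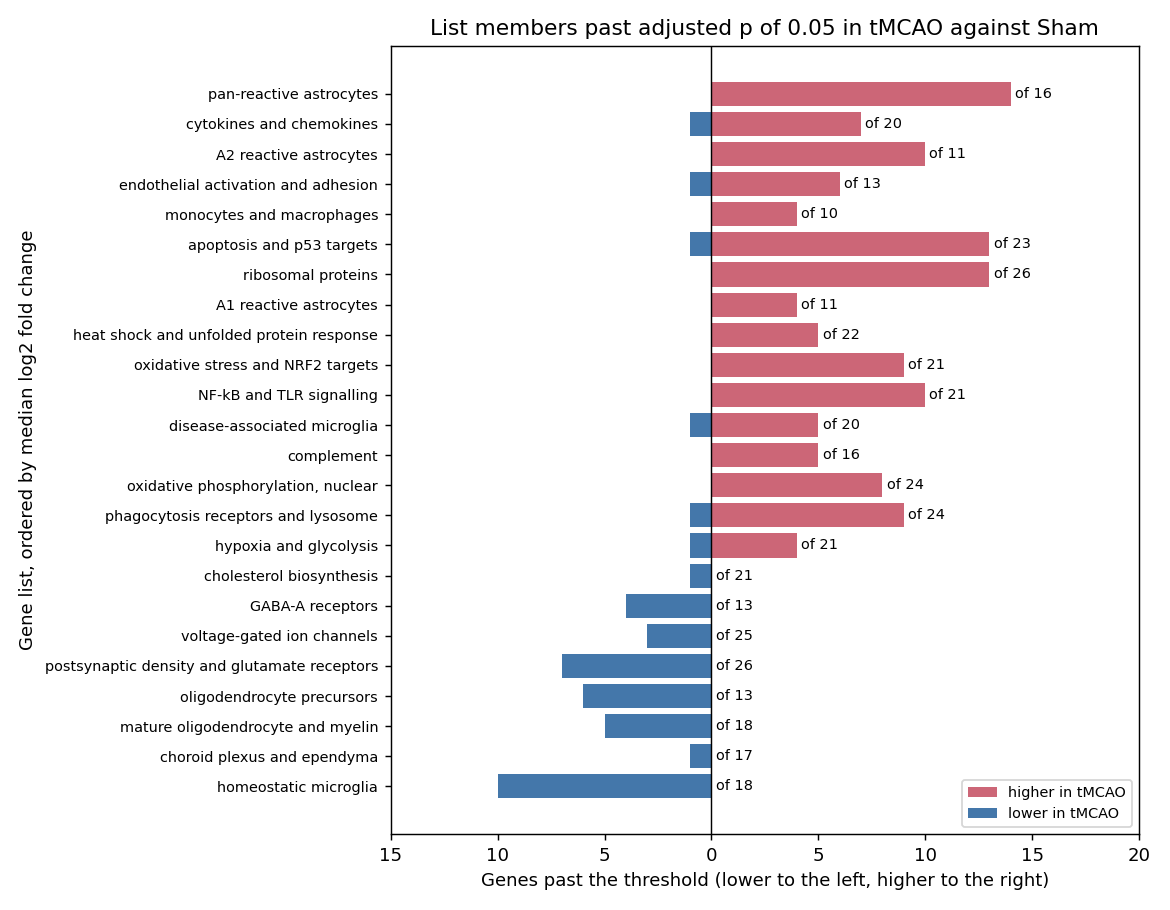
Number of genes past the threshold in each of the 24 lists with a camera adjusted p below 0.05 at the preset correlation, higher in tMCAO to the right and lower to the left, with the number tested beside each bar. Pan-reactive astrocyte genes stand at 14 of 16 higher and homeostatic microglial genes at 10 of 18 lower.

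In all, 24 of 48 lists passed camera with the preset correlation, 16 higher and 8 lower in tMCAO. With an estimated correlation 0 lists passed (lowest adjusted p = 0.58), and fry called 12 lists, 10 of them among the 24. At a fry adjusted p of 0.02 these were the homeostatic microglial, NF-kB and p53 lists. Phagocytosis (0.03), pan-reactive astrocytes (0.031) and complement (0.045) followed, with A2, monocytes, NRF2 and hypoxia at 0.041 each. Outside the 24, fry called proliferation (0.02, higher) and mural cells (0.041, lower).

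The libraries also differed by markers of brain regions within each group. The first principal component (56.3% of variance) separated the groups, and the second (25.1%) set Sham 2 and tMCAO 3 (-11.6 and -30.6) apart from the other libraries (6.9 to 12.8). Drd2, a dopamine receptor of striatal neurons, was at 25.6 FPKM in Sham 2 and 16.0 in tMCAO 3, against 2.87 to 5.54 elsewhere. Ttr, transthyretin of the choroid plexus, was at 20.0 and 6.01 FPKM in these libraries and at 343 to 706 elsewhere. Drd2 and Ttr were chosen after their values were seen. No striatal gene of 14 and no thalamic gene of 12 passed, also adjusted over the list alone (camera adjusted p = 0.19 and 0.29). With the estimated correlations of 0.98 and 0.62, camera gave adjusted p of 0.82 and 0.81. Calls of these lists at the preset correlation of 0.01, in any setting, are therefore weak evidence. The same holds for preset calls of the called lists whose estimated correlation was above 0.62. These were the ribosomal (0.94), heat shock (0.81), mature oligodendrocyte (0.79), choroid plexus (0.76), respiratory chain (0.73), pan-reactive astrocyte (0.69), A2 (0.67) and cytokine lists (0.66). With the striatal covariate, Ppp1r1b passed as higher (limma adjusted p = 0.0057) and Slc17a6 as lower (0.03). Ppp1r1b itself belongs to the list behind that covariate. The striatal list passed as lower without Sham 1 (0.034), Sham 3 (0.049) or tMCAO 3 (0.0051), and the thalamic list passed without Sham 2 (0.0055). Choroid plexus genes had 1 of 17 lower (1 adjusted over the list alone), with a camera adjusted p of 0.04, 0.77 with an estimated correlation, and 0.18, 0.17, 0.081 and 0.43 without Sham 1, Sham 3, tMCAO 2 and tMCAO 3. This call was also lost with a pseudocount of 0.1 (0.067), at a mean FPKM of at least 2 (0.34), when rescaled (0.14), with quantile normalization (0.066) and with voom (0.075). Cortical layer genes had 1 higher and 1 lower of 13, the same adjusted over the list alone (camera adjusted p = 0.48). None of 3 erythrocyte genes passed, and 1 was lower adjusted over the list alone. Without Sham 2 and tMCAO 3, chosen after seeing the data, 2121 genes passed, 1227 higher and 894 lower, and the striatal (camera adjusted p = 3.7e-05) and thalamic lists (0.048) passed as lower. The thalamic list also passed as lower with a striatal covariate (0.0032). Without these libraries 24 of the 149 named calls were lost, among them Vegfa (adjusted p = 0.068), Gpr17 (0.087) and Aif1 (0.1).

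**Figure D4:**
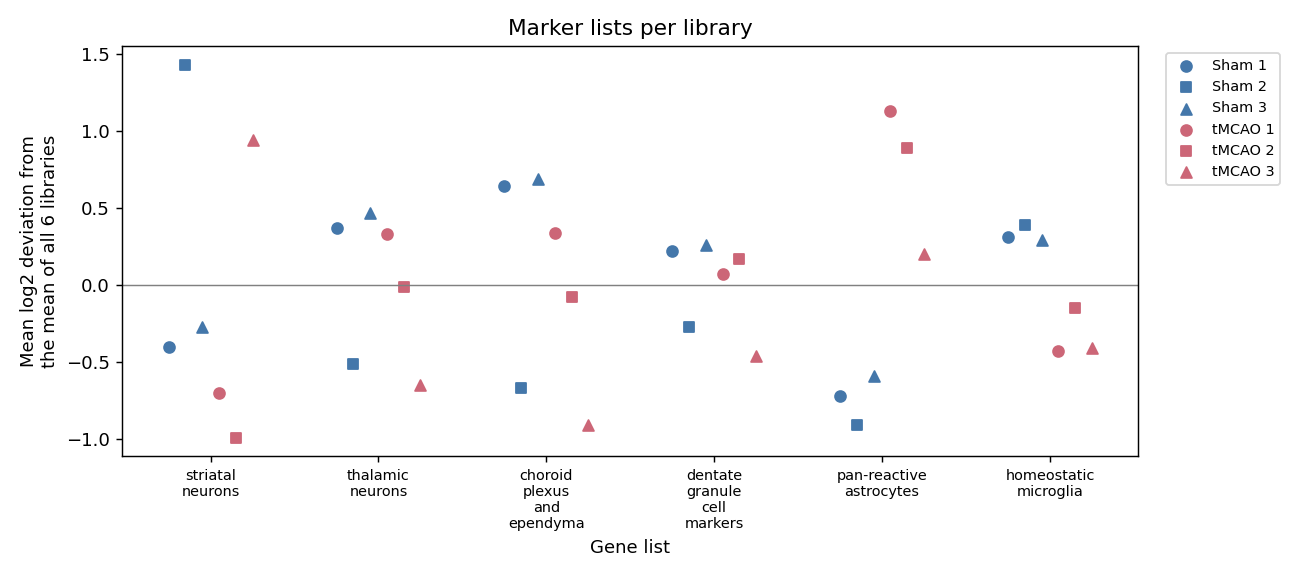
Mean log2 deviation of 6 marker lists from the mean of all 6 libraries, 1 point per library. Sham 2 (1.43) and tMCAO 3 (0.94) lie above the other libraries for striatal genes, while tMCAO 3 (0.2) lies above the Sham libraries (-0.91 to -0.59) for pan-reactive astrocyte genes.

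The authors' deposited table holds 4583 genes with an adjusted p below 0.05, 2453 higher and 2130 lower in tMCAO. Of the 3947 of these genes that were tested here, 2695 passed here in the same direction and 0 in the opposite direction. Both comparisons rest on the same 6 libraries. Across genes, the authors' log2 fold change (Sham over tMCAO) had a correlation of -1.0 with the log2 ratio of mean FPKM (tMCAO over Sham). Opposite directions could therefore hardly occur, and their absence is no independent evidence.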

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

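The results in this part were picked out after the data were seen, and no explanation of them was tested. Haemoglobin genes are among those left out of the comparison table and so took no part in the comparison. In tMCAO 1 they stood above each Sham library: Hbb-bs at 207 FPKM, Hba-a1 at 88.9, Hba-a2 at 21.8 and Hbb-bt at 19.8. In Sham, Hbb-bs lay between 4.26 and 9.68 FPKM, and in tMCAO 2 and 3 it was at 1.69 and 2.4 FPKM. Hbb-bs and Hbb-bt are similar beta-globin genes and Hba-a1 and Hba-a2 similar alpha-globin genes, so the division of reads within each pair is uncertain. Among 271 genes left out of that table with a mean FPKM of at least 0.5, 18 passed the limma test in the table of all genes, and 9 of them were higher in tMCAO. They include short RNAs such as Snord42b, listed at 0 in all Sham libraries and at 1.598 to 2.477 FPKM in tMCAO, which poly(A) selection measures poorly.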

How the results depend on the processing

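Voom on recovered reads, thinning, removal of the exon length trend, the striatal covariate and the fit without Sham 2 and tMCAO 3 were chosen after seeing the data, and so was the count over other splits. With library weights 4913 genes passed (2681 higher, 2232 lower), for which the cause was not tested. Requiring a log2 fold change of at least 1 left 239 (177 and 62), a stricter rule by construction. That count was 612 (369 and 243) with a pseudocount of 0.1, 503 (271 and 232) when rescaled, which also makes the pseudocount smaller against the values, 640 (350 and 290) with voom and 61 to 339 without 1 library. Leaving out 1 library each gave 75 to 3896 genes (58 to 2174 higher, 17 to 1722 lower) and 21 to 26 lists (14 to 18 higher, 7 to 10 lower), with fewer samples in each fit. The lowest gene counts came without Sham 3 (75) and Sham 1 (124). In the other planned and added settings the gene totals lay between 2121 and 3941, within 1.5 times the main count. Median-ratio scaling gave 2826 genes, 2813 of them among the 2847 in the same direction, so it hardly differed from the deposited scaling. With an estimated correlation 0 lists passed (0 higher, 0 lower), and fry called 12 (10 higher, 2 lower). At a mean FPKM of at least 2, 10 lists passed as higher, with fewer genes tested. Of the 24 called lists 16 passed there and 7 lost their call (cytokines, complement, phagocytosis, oligodendrocyte precursors, endothelial activation, hypoxia and choroid plexus), while the monocyte list had too few genes for a test. Quantile normalization ended 2 of the 24 calls (hypoxia, choroid plexus), rescaling 2 (precursors, choroid plexus), the fit without Sham 2 and tMCAO 3 2 (precursors, cholesterol), and removal of the length trend (precursors), library weights (precursors), voom (choroid plexus), the pseudocount of 0.1 (choroid plexus) and no filter (cholesterol) 1 each. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, gave 2847 genes, and the highest other count was 0. For lists, 4 of the 10 splits gave at least 24, the highest other split 30. That split set Sham 1, Sham 2 and tMCAO 3 against the rest. The splits that joined tMCAO 3 to Sham 1 and Sham 3, or to Sham 2 and Sham 3, gave 29 lists each. The list count alone thus does not mark out the real groups, and the cause was not tested. With 10 splits a share under 0.05 cannot be reached. Signs turned only for genes and lists that had not passed in the comparison of all 6 libraries, with adjusted p of 0.46 or more for genes in the fits where the sign turned; the cause was not tested. The log2 fold change of Abhd12 was -0.01 with quantile normalization and that of mt-Co1 -0.01 when rescaled to an equal sum. Leaving out single libraries, the log2 fold change of mt-Cytb ran from -0.0017 to 0.19. Trbc2 ran from -0.56 to 0.16 and was at 0.07 with the striatal covariate. Penk ran from -1.59 to 0.02 and was at 0.02 with that covariate. Ppp1r1b ran from -0.7 to 0.8 and was at -0.1 with library weights. Calb2 ran from -0.8 to 0.19 and was at 0.04 without Sham 2 and tMCAO 3, and Slc17a6 ran from -0.95 to 0.39. For lists whose direction turned, the camera adjusted p over fits without 1 library ran from 0.48 to 0.98 for purinergic genes, 0.16 to 0.98 for astrocyte markers, 0.73 to 0.98 for pyramidal markers, 0.25 to 0.85 for inhibitory markers, 0.48 to 0.98 for neurogenesis, 0.0051 to 0.87 for striatal genes and 0.21 to 0.99 for mitochondrially encoded genes. The striatal list turned without Sham 2 (0.87) and passed as lower without Sham 1, Sham 3 or tMCAO 3. Other turns came for purinergic genes without a filter (0.71) and without Sham 2 and tMCAO 3 (0.88), for astrocyte (0.92) and pyramidal markers (0.99) with quantile normalization, for pyramidal (0.87) and inhibitory markers (0.88) with the covariate, and for neurogenesis when rescaled (0.97) and without Sham 2 and tMCAO 3 (0.95). Depth limits low genes such as Cnr2, with 33 reads over the Sham libraries.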

Other observations

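All tests of explanations in this part were chosen after the result had been seen, and the 3 further gene lists were composed after the leading genes were known. Genes listed as glucocorticoid-responsive stood high in tMCAO: 17 of 22 rose and none fell, with a median log2 fold change of 1.55. The members that did not pass were Tsc22d3 (limma adjusted p = 0.21), Zbtb16 (0.4), Klf9 (0.16), Hif3a (0.23) and Sult1a1 (0.051). Among the risers, Cdkn1a, Nfkbia and Mt2 were also counted in the p53, NF-kB and NRF2 lists, so the rise is not particular to glucocorticoid targets. Because the glucocorticoid list holds genes seen to lead the comparison, such as Cdkn1a, Sgk1, Nfkbia and Angptl4, its camera p of 5.5e-16 (p = 0.037 with an estimated correlation) is no independent evidence. Sgk1, a kinase induced by steroid hormones and chosen here after its values were seen, rose from 11.2 ± 0.788 to 49.0 ± 9.2 FPKM. Transporter genes of brain endothelium fell in 11 of 20 cases and rose in 3, with a median of -0.39 (camera p = 0.0042, and p = 0.06 with an estimated correlation), and this list too was built around genes seen to fall. Slco1c1, a thyroid hormone transporter, fell from 10.7 ± 0.508 to 4.18 ± 0.898 FPKM. The median over 8 endothelial identity genes was 0.03. Its 95% bootstrap interval (-0.43 to 0.5, resampling genes and not libraries) covers both no change and the median of the transporters.

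Homeostatic microglial genes were lower in tMCAO, with a median of -0.73. Of 37 other microglia-enriched genes, 6 rose and 4 fell, with a median of 0.06 (95% bootstrap interval -0.07 to 0.32, resampling genes and not libraries). A loss of microglia as the only change would lower them by about as much as the homeostatic genes, and they did not fall together. A rise of some members could hide a loss of cells, so the median cannot exclude one. Some of these genes had been looked at before the list was made. The trend on exon length is argued against, since the median of the homeostatic genes was -0.77 after its removal. Blood monocytes that replace lost microglia stay open: the monocyte and macrophage list had a median of 0.63 but an adjusted p = 0.58 with an estimated correlation, and activated microglia express some of its genes, so a change of state and a change of cells after tMCAO cannot be told apart here. Genes of blood monocytes, chosen after their values were seen, were low and did not move alike. Ccr2 was at 0.0545 ± 0.0281 FPKM in Sham and 0.0697 ± 0.0414 FPKM in tMCAO (exact permutation p = 0.6). Ly6c2 had 3 and 4 reads in all, and Plac8 had 6 and 19. Chil3 had 15 and 187 reads in all (exact permutation p = 0.6), 174 of them in tMCAO 1. Haemoglobin was also highest in tMCAO 1 (Hbb-bs at 207 FPKM).

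In tMCAO, 13 of 26 ribosomal protein and 8 of 24 respiratory chain genes were higher, and 3 of 25 ion channel and 7 of 26 postsynaptic genes lower, with adjusted p of 0.59, 0.68, 0.6 and 0.6 for these lists with an estimated correlation. The trend on exon length does not account for the whole of this: after its removal the medians of the lists were 0.45, 0.22, -0.21 and -0.23, against 0.49, 0.26, -0.28 and -0.3 before. Thinning all libraries to the shallowest left 0.48, 0.25, -0.28 and -0.3. Thinned values were scaled back to the same expected FPKM, so medians of well-covered genes could hardly move. This test therefore cannot decide on depth, or on anything else that differed with it between the groups. RNA integrity was not tested and stays open, as does an effect of tMCAO itself, and the ribosomal score of tMCAO 3 (0) was lower than those of tMCAO 1 and 2 (0.46 and 0.31).

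Striatal genes were high in Sham 2 and tMCAO 3. If these libraries held a different piece of tissue, genes of dentate granule cells should be lower in them, and they were, by a mean of -0.55 on the log2 scale relative to the other libraries of their group. A dissection that differed between libraries and reached beyond the hippocampus is a hypothesis that this leaves standing. The thalamic score was -0.51 in Sham 2 and -0.65 in tMCAO 3, against -0.01 to 0.47 in the other libraries. Markers of another region thus stood higher in the other libraries, so which libraries held hippocampus alone cannot be told. Exchanged group labels are argued against by the pan-reactive astrocyte score of tMCAO 3, which was 0.2 against -0.91 to -0.59 in the Sham libraries. The design names no group that would give a biological explanation, and none was tested.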
